A study of Mus musculus with 24 samples.

How the data were processed

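RNA-seq counts of cytoplasmic and RNP granule fractions of NIH3T3 cells were used, in 24 libraries and 10 groups. Per the labels' protocols, RNA was taken up in Trizol, ribosomal RNA was depleted and directional libraries were made. The deposited count values were made by the authors with TopHat and bedtools on mm10, per the submitters' processing notes, which name no versions. Groups and replicate numbers came from the labels. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The dose and duration of each stress are not given in the sources used here.

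The tables held 34739 RefSeq transcripts of 24172 symbols, and 0 columns of other samples. The transcript with the highest total was kept for each symbol. Counts covered the whole span of a transcript, introns included: 109 of 115 isoform pairs with the same span had equal counts (at least 500 reads and 200 bases of exon difference). Nested genes showed that a read could count for several transcripts. A host gene was lower than its nested gene in 0 of 110 pairs on the same strand and in 2 of 153 on opposite strands, so strand appeared not to be used. Overlapping partners are therefore named beside some genes. Coordinates are those of the files (mm10). Lengths and biotypes came from GENCODE M21, matched by accession for 23613 symbols, by symbol for 337 and by older symbol for 19, with 203 unmatched.

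Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The model had 1 mean per group over 24 libraries, so that groups of 2 shared the estimate of spread with the others. Robust quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05 were run on 15616 genes for 17 contrasts. Redistribution is the interaction of fraction and stress. CPM values used TMM sizes, and log2 CPM a prior count of 2. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Members were also adjusted over the list alone. The lists covered the unfolded protein response, heat shock, oxidative stress, immediate early genes, proto-oncogenes, cholesterol synthesis, extracellular matrix, giant proteins, cell cycle, translation factors, nuclear noncoding RNA, small structural RNA, ribosomal proteins, oxidative phosphorylation, replication-dependent histones, markers of immune, epithelial and endothelial cells, mRNA length and 3' untranslated motifs.

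The comparisons, the tests, the gene lists and the alternatives named here were set before the data were examined, except those named as added in the closing section. Named genes were, at a mean log2 CPM of at least 3 and an adjusted p under 0.05, the 6 highest and 6 lowest fold changes (3 and 3 for granule contrasts and differences between stresses), plus up to 4 members of a described list with the smallest adjusted p. Clone names, predicted genes and ribosomal RNA were left out of the extremes, and a few genes that the rule names are not reported here. Alternatives were RLE factors, library size alone, leaving out structural RNA, DESeq2 1.42.0, no filter, a filter of 1 CPM, the replicate number as a block, a fit to the compared libraries alone and leaving out each replicate or library.

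Replicate numbers were checked for pairing. Deviations from the group means correlated between same-numbered DMSO and THAP libraries at r = 0.47 to 0.91, and 12 of 12 libraries correlated best with their own number. The blocked count is therefore given beside the DMSO and THAP counts. The p-values of single genes and lists come from the model without the block unless the block is named. Counts and calls with a library left out ignore the pairing as well.

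The procedure was tested on simulated data with 100 changed genes per fold size. For redistribution it recovered 2% of 2-fold and 38% of 4-fold changes with THAP (15001 genes), 0% and 5% with HS (15030 genes) and 0% and 12% with AS (15002 genes). Of the calls, 0% were genes that had not been changed. In these simulations, most 4-fold changes of redistribution were thus missed by single-gene tests. The simulated data gave 40, 5 and 12 calls with THAP, HS and AS, where the real data gave 271, 721 and 706. Recovery depends on how many genes change, so the share missed in the real data may differ.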

Results

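RNA of the mouse fibroblast line NIH3T3 was sequenced from a cytoplasmic fraction and from a fraction of ribonucleoprotein (RNP) granules, the assemblies of RNA and protein that gather untranslated mRNA. The 24 libraries formed 10 groups. Thapsigargin (THAP), which blocks the calcium pump of the endoplasmic reticulum, and its solvent control DMSO each had 3 libraries per fraction. Heat shock (HS), the oxidant arsenite (AS) and their shared control H2O each had 2 libraries per fraction. The dose and the duration of each stress are not given in the sources used here. Counts summed over genes ranged from 6.21 M (HS cytoplasm 2) to 39 M (AS granule 1) per library, with a median of 14 M. The series asked which mRNAs change their place in the cell under stress. The RNAs were therefore compared between fractions within a treatment, between each stress and its control within a fraction, and as the change of the granule-to-cytoplasm ratio between each stress and its control, here called redistribution.

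The first principal component, with 42.3% of the variance, ran from the replicate 3 cytoplasm libraries of THAP and DMSO (-118 and -106) to the AS granule libraries (141 and 145). Within each group and replicate number the granule library lay above its cytoplasm library on it. The second component, with 23.5%, set the 4 libraries numbered replicate 3 (DMSO and THAP, both fractions) apart from all others. Replicates of a group correlated at r = 0.902 to 0.926 across genes where a pair included replicate 3, and at 0.924 to 0.988 otherwise. No pair of libraries held identical values (0 pairs). The granule libraries of replicate 2 in the H2O, HS and AS groups carried 4.22%, 2.44% and 1.88% of their counts on Rn45s, the ribosomal RNA precursor gene, against at most 0.911% in the other libraries.

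**Figure D1:**
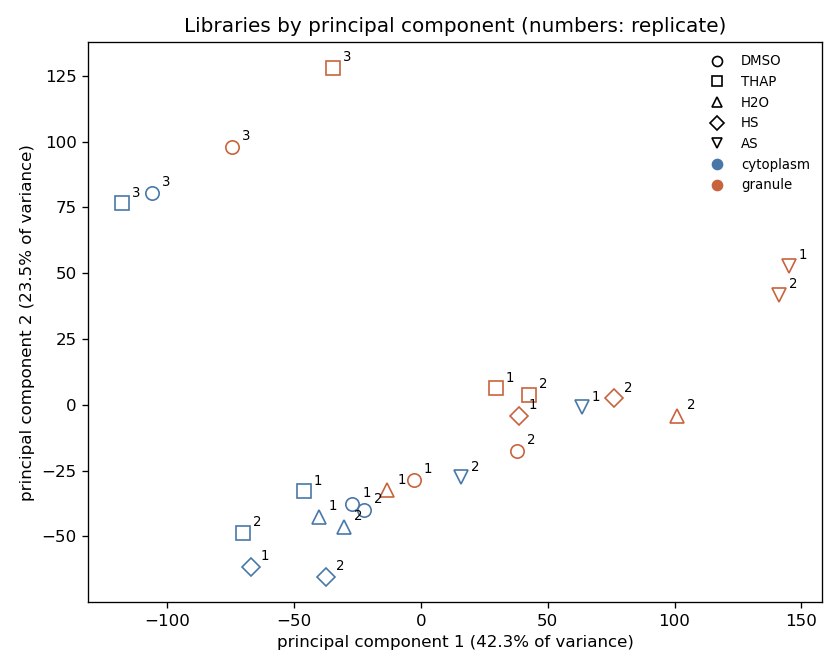
Principal components 1 and 2 of log2 CPM, with the percentage of variance on each axis; each point is 1 of 24 libraries, blue marks the cytoplasm, orange the granule fraction, shapes the treatment and numbers the replicate. The replicate 3 libraries of DMSO and THAP lie above the others on component 2, and the AS granule libraries lie farthest right on component 1.

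In unstressed cells, Neat1 and some mRNAs of very large proteins had higher levels in the granule fraction than in the cytoplasm, and some small RNAs and ferritin mRNA had lower ones. With DMSO, Neat1, the scaffold RNA of nuclear paraspeckles (19, 5824708 to 5845478, mm10), stood at 757 CPM ± 732 (SD, n = 3) in granules and 93.6 ± 47.5 in cytoplasm, 8.08-fold higher (log2 ratio 3.01 ± 0.71, SE; edgeR adjusted p = 0.0435). Macf1, which encodes a giant linker of actin and microtubules, was 2.49-fold higher, Myh9, a nonmuscle myosin heavy chain, 1.95-fold and Mut, the mitochondrial methylmalonyl-CoA mutase, 2.86-fold. Lower in granules were the vault RNA Vaultrc5 (log2 ratio -2.98 ± 0.43), the ribonuclease P RNA-like Rprl3 (-2.18 ± 0.47), the ferritin light chain gene Ftl1 (-1.66 ± 0.33) and the stress transcription factor gene Atf4 (-1.10 ± 0.26). Of 40 mRNAs of giant proteins, 3 were higher over all genes and 24 adjusted over the list alone (camera adjusted p = 6.61e-16, or adjusted p = 0.229 with an estimated correlation). Of 35 extracellular matrix and secretory genes, 1 was higher, Lamc1 (laminin gamma 1, 1.65-fold), and 7 were adjusted over the list alone (camera adjusted p = 1.54e-06, or adjusted p = 0.425 with an estimated correlation). Of 28 cell-cycle genes, 1 was higher, Rrm1 (ribonucleotide reductase, 1.67-fold; camera adjusted p = 0.00158, or adjusted p = 0.613 with an estimated correlation).

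By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 202 of 15616 genes differed between the DMSO fractions, 30 higher and 172 lower in granules. With the replicate number as a block, 1651 did (516 higher, 1135 lower), and the 202 were called again in the same direction. Leaving out 1 DMSO library gave 60, 5 and 65 calls (cytoplasm 1, 2 and 3) and 42 and 9 (granule 1 and 2), and none of the 18 genes followed up kept its call without each of the 6 libraries in turn. With the spread estimated from the DMSO libraries alone, edgeR called 0 genes (2201 at an unadjusted p under 0.05), and DESeq2 on all 24 libraries called 835.

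With H2O, Vaultrc5 was 15.2-fold lower in granules (log2 ratio -3.92 ± 0.55, n = 2; edgeR adjusted p = 0.00369), and Ftl1 and the ferritin heavy chain gene Fth1 were 5.44-fold and 4.26-fold lower. Neat1 was 8.52-fold higher, Malat1, an abundant RNA of nuclear speckles, 4.59-fold, Macf1 4-fold and Atm, the kinase of the DNA damage response, 5.24-fold. None of these 4 kept its call without H2O granule 2, where the log2 ratios were 1.91, 0.25, 1.43 and 1.47. Malat1 stood at 305 and 438 CPM in cytoplasm and at 420 and 2880 in granules 1 and 2. The highest ratio was that of Mecom, a zinc finger transcription factor gene (log2 3.96 ± 1.03), followed by the overlapping genes Kcnq1ot1 and Kcnq1 (3.81 ± 0.88 and 3.75 ± 0.88), whose reads could not be told apart. Of 40 giant-protein mRNAs, 23 were higher and 30 adjusted over the list alone (camera adjusted p = 2.09e-12, or adjusted p = 0.462 with an estimated correlation). Of 81 ribosomal protein mRNAs, 13 were lower, among them Rps2 (-1.61 ± 0.41) and Rpl12 (-1.44 ± 0.34), and 59 adjusted over the list alone (camera adjusted p = 2.44e-22, or adjusted p = 0.578 with an estimated correlation). The chaperone gene Hsp90aa1 (5.32-fold) and the proliferation marker gene Mki67 (6.82-fold) were higher as well. The sizes of these ratios also moved over the alternatives and left-out libraries or replicates. The log2 ratio ranged over 1.56 to 3.01 for Hsp90aa1 and 1.58 to 3.44 for Mki67. It ranged over -2.28 to -1.10 for Rps2 and -2.21 to -0.89 for Rpl12. Of 26 heat-shock genes, 5 were higher (5 adjusted over the list alone, camera adjusted p = 0.0539, or adjusted p = 0.578 with an estimated correlation), and 6 of 28 cell-cycle genes (6 alone, camera adjusted p = 0.0436, or adjusted p = 0.633 with an estimated correlation).

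The H2O fractions differed in 1572 genes (1004 higher in granules, 568 lower; edgeR's quasi-likelihood test). Single libraries decided this count. It was 7 without cytoplasm 1, 0 without cytoplasm 2, 5306 without granule 1 and 2 without granule 2, where the log2 ratio of Mecom was 1.02. With the spread of the H2O libraries alone, edgeR called 0 genes (1699 at an unadjusted p under 0.05), while DESeq2 on all libraries called 2920. Scaling by library size alone put 47.9% of the calls on the higher side against 63.9% with TMM.

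In stressed cells, ribosomal protein and oxidative phosphorylation mRNAs were called on the cytoplasmic side. Giant-protein mRNAs were called on the granule side, as 23 of 40 were with H2O. Calls over all genes numbered 202 with DMSO and 1572 with H2O, against 4800, 5336 and 4211 after THAP, HS and AS. List counts alone therefore do not show a change between treatments, which is tested below as redistribution. After THAP, 29 of 40 giant-protein mRNAs were higher in granules than in cytoplasm (33 adjusted over the list alone; camera adjusted p = 1.75e-15, or adjusted p = 0.126 with an estimated correlation), after HS 26 (27 alone, or adjusted p = 0.2 with an estimated correlation) and after AS 22 (29 alone, or adjusted p = 0.183 with an estimated correlation). Ribosomal protein mRNAs lay on the cytoplasmic side, with 43, 80 and 80 of 81 lower in granules after THAP, HS and AS (63, 81 and 81 adjusted over the list alone; adjusted p = 0.53, 0.2 and 0.183 with an estimated correlation). Of 74 nuclear-encoded genes of oxidative phosphorylation, 46, 67 and 71 were lower (56, 68 and 71 adjusted over the list alone; adjusted p = 0.494, 0.282 and 0.183 with an estimated correlation). Of 20 translation factor and related genes whose mRNAs carry 5' terminal oligopyrimidine tracts, 14, 18 and 18 were lower (16, 19 and 18 adjusted over the list alone, or adjusted p = 0.197, 0.133 and 0.131 with an estimated correlation). Replication-dependent histone mRNAs were lower in 67 of 69 cases after HS and after AS, and in 0 after THAP (camera adjusted p = 0.000117, or adjusted p = 0.759 with an estimated correlation). Of 11 nuclear noncoding RNAs, 5 were higher after THAP (camera adjusted p = 0.0196, or adjusted p = 0.47 with an estimated correlation).

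Between the fractions, 4800 genes differed after THAP (2515 higher in granules), 5336 after HS (2491 higher) and 4211 after AS (1391 higher; edgeR's quasi-likelihood test); with the replicate block, the THAP count was 7665. Single libraries moved these counts by more than 1.5 times: THAP cytoplasm 2 left out gave 2956, HS cytoplasm 1, cytoplasm 2 and granule 2 gave 2608, 3524 and 2323, and AS cytoplasm 2, granule 1 and granule 2 gave 1197, 1558 and 2737. Scaling by library size alone, which raised the median ratio of all genes by 0.17, 0.48 and 0.13 (log2) after THAP, HS and AS, moved the share of higher calls from 52.4% to 66.3% after THAP and from 46.7% to 75.1% after HS.

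In the cytoplasm, THAP raised 9 of 29 unfolded protein response mRNAs and 9 of 23 immediate early mRNAs and lowered 8 of 40 giant-protein mRNAs (adjusted p = 0.062, 0.014 and 0.138 with an estimated correlation). Herpud1, an endoplasmic reticulum protein of the degradation pathway for misfolded proteins (NM_022331, 8, 94386438 to 94395377, mm10), rose 8.39-fold, from 92.6 CPM ± 8.5 (SD, n = 3) with DMSO to 777 ± 271 (log2 fold change 3.07 ± 0.34, SE; edgeR adjusted p = 8.99e-05). Ddit3, the stress transcription factor CHOP, rose 7.59-fold (2.92 ± 0.25; edgeR adjusted p = 5.53e-06). Its span overlaps Mars. Chac1, a glutathione-degrading enzyme, rose 10.7-fold and Syvn1, a ubiquitin ligase of the endoplasmic reticulum, 2.71-fold. Gadd45g, a growth arrest gene (13, 51846678 to 51848468), had the largest rise, 22.8-fold, from 15.2 CPM ± 6.80 to 346 ± 168 (4.51 ± 0.60; edgeR adjusted p = 0.000463). The transcription factor genes Nr4a1 (11.9-fold), Atf3 (9.36-fold), Egr1 (9.15-fold), Junb (8.24-fold, overlapping Prdx2) and Klf6 (2.93-fold) rose too, as did Gadd45b (6.90-fold). Ahnak, which encodes a giant scaffold protein (NR_104460, 19, 8989284 to 9076914), fell 5.88-fold, from 2510 CPM ± 1050 to 427 ± 245 (-2.56 ± 0.47; edgeR adjusted p = 0.00621). Golgb1, the Golgi tether giantin, and Herc2, a ubiquitin ligase, fell 3.66-fold and 2.95-fold.

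Of 29 unfolded protein response genes, 9 rose and 17 adjusted over the list alone (camera adjusted p = 6.9e-14, or adjusted p = 0.062 with an estimated correlation). Of 23 immediate early genes, 9 rose and 17 adjusted over the list alone (camera adjusted p = 8.14e-20, or adjusted p = 0.014 with an estimated correlation). Of 40 giant-protein mRNAs, 8 fell and 25 adjusted over the list alone (camera adjusted p = 3.17e-13, or adjusted p = 0.138 with an estimated correlation). Of 69 histone genes, 2 rose over all genes, Hist1h1a (3.77-fold) and Hist3h2a (2.89-fold), and 66 adjusted over the list alone (camera adjusted p = 3.23e-30, or adjusted p = 0.387 with an estimated correlation). Among 21 oxidative stress genes, Slc3a2, an amino acid transporter subunit, rose 2.56-fold and Hmox1, heme oxygenase 1, fell 2.61-fold. The matrix receptor gene Itgb1 fell 2.29-fold, the receptor tyrosine kinase gene Met 2.55-fold, the glutathione transferase gene Gstm1 4.03-fold and the cyclin gene Ccnb1 1.55-fold. Of 28 cell-cycle genes, 1 fell (3 adjusted over the list alone, camera adjusted p = 0.0232, or 0.0543 with the replicate block, or adjusted p = 0.695 with an estimated correlation).

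In all, 444 genes changed in the cytoplasm with THAP, 279 up and 165 down (edgeR's quasi-likelihood test), and 1917 with the replicate block (942 up, 975 down). Leaving out DMSO cytoplasm 1, 2 or 3 gave 121, 174 and 255 calls, and THAP cytoplasm 1, 2 or 3 gave 238, 146 and 278. Of the 28 genes followed up, 13 kept their calls without each of the 6 libraries, among them Gadd45g, Chac1, Herpud1, Ddit3, Junb and Ahnak. The spread of these groups alone gave 190 calls and DESeq2 912.

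**Figure D2:**
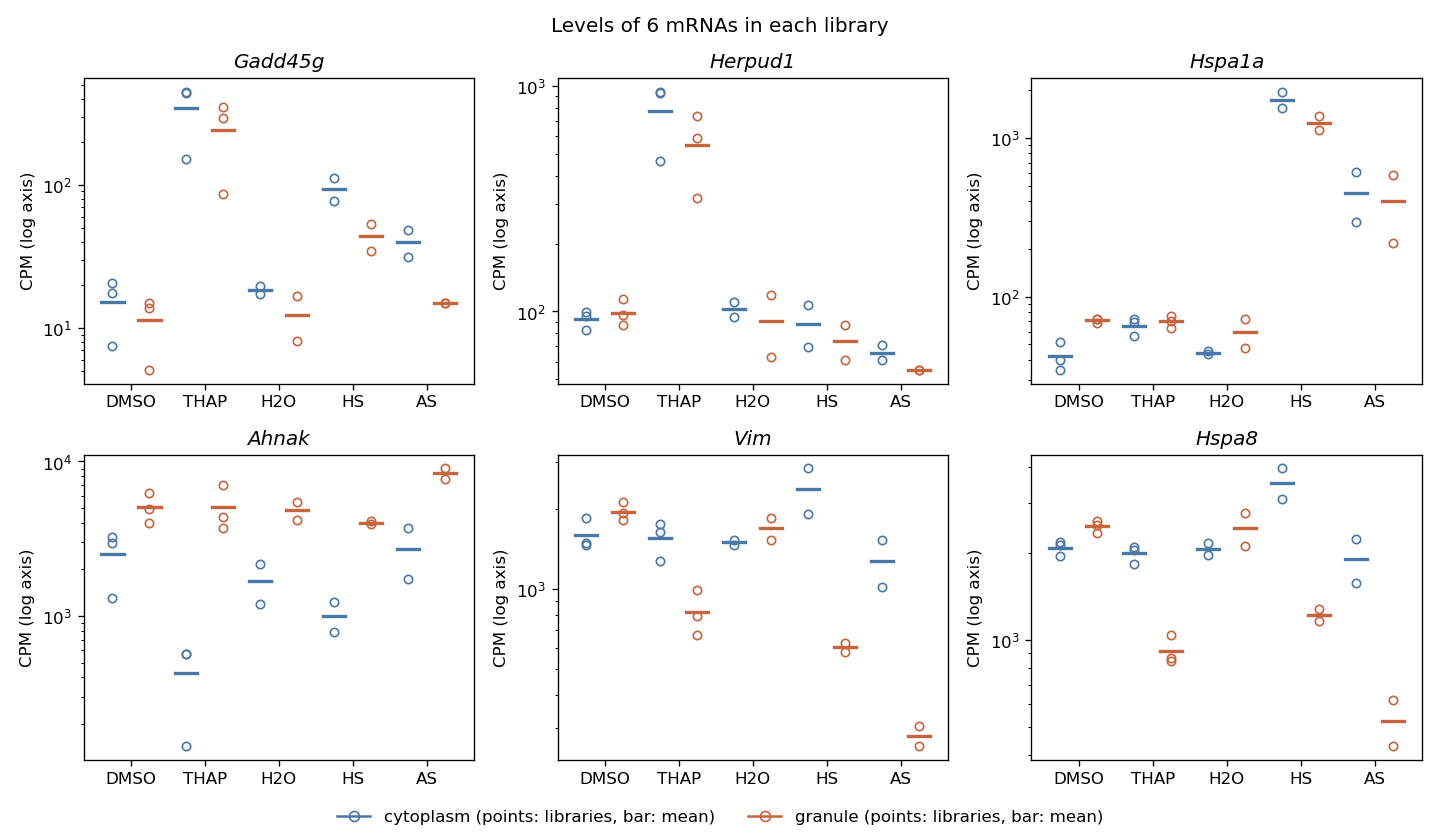
Levels of 6 mRNAs in CPM (log axis) in each library of 10 groups; points are libraries, bars group means, blue the cytoplasm and orange the granule fraction. Gadd45g and Herpud1 stood higher with THAP in both fractions, Hspa1a with HS and AS, and Vim and Hspa8 stood lower in granules than in cytoplasm after each stress.

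Heat shock raised heat-shock mRNAs in the cytoplasm. Hspa1a, an inducible HSP70 chaperone gene (NM_010479, 17, 34969190 to 34972156, mm10), rose 39.2-fold, from 44.5 CPM ± 1.40 (SD, n = 2) with H2O to 1740 ± 273 (log2 fold change 5.29 ± 0.44, SE; edgeR adjusted p = 3.73e-06). Its near-identical copy Hspa1b rose 38.0-fold and the adjacent family member Hspa1l 33.4-fold, and the counting leaves open how the reads of these 3 genes divide. Dnajb1, an HSP40 cochaperone gene, rose 3.90-fold. Dlgap1, a postsynaptic scaffold gene (17, 69969073 to 70821413), rose 56.5-fold, from 12.1 CPM ± 3.74 to 687 ± 28.0, and Atf3 rose 10.8-fold. Ccnf, a cyclin of the F-box family, fell 3.46-fold, Kmt2d, a histone methyltransferase, 4.09-fold, and among 40 proto-oncogenes Ski and Mdm2 fell 2.57-fold and 2.40-fold (camera adjusted p = 0.000396, or adjusted p = 0.128 with an estimated correlation). Of 26 heat-shock genes, 3 rose and 13 adjusted over the list alone (camera adjusted p = 1.73e-12, or adjusted p = 0.00913 with an estimated correlation).

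Arsenite raised the same HSP70 genes, Hspa1a 10.2-fold to 452 CPM ± 219 (log2 3.35 ± 0.41, n = 2; edgeR adjusted p = 0.00137), Hspa1b 9.82-fold and Hspa1l 8.97-fold. Other stress genes had large fold changes (n = 2) that missed the threshold by edgeR's test without a block: Hsph1, an HSP110 chaperone gene, at 2.00 ± 0.51 (edgeR adjusted p = 0.113), Hsp90aa1 at 1.80 ± 0.48 (0.115), Hmox1 at 1.52 ± 0.38 (0.113), Klf6 at 1.62 ± 0.28 (0.0692), Egr1 at 2.10 ± 0.74 (0.151) and Pabpc1, the poly(A)-binding protein gene, at 2.31 ± 0.68 (0.126). With the replicate number as a block, edgeR called 1765 genes in cytoplasm with AS. The named results that had missed the threshold were called with it. The values do not show that the numbers pair these libraries. Of 26 heat-shock genes, 2 rose and 6 adjusted over the list alone (camera adjusted p = 0.0266, or adjusted p = 0.426 with an estimated correlation). Of 23 immediate early genes, 0 rose by edgeR and 1 adjusted over the list alone (camera adjusted p = 0.000807, or adjusted p = 0.426 with an estimated correlation).

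In the cytoplasm 236 genes changed with HS, 107 up and 129 down, and 3 with AS, the 3 HSP70 genes (edgeR's quasi-likelihood test; 3452 genes at an unadjusted p under 0.05 with AS, and 840 by DESeq2). The HS count was 7 and 6 without H2O cytoplasm 1 or 2 and 37 and 23 without HS cytoplasm 1 or 2. Of the genes followed up, 4 of 15, Hspa1a, Hspa1b, Hspa1l and Dlgap1, kept their calls in each case. The AS count was 0 without either H2O cytoplasm library and 11 without AS cytoplasm 2. With the spread of the compared groups alone the counts were 916 and 2492, and DESeq2 called 381 with HS. Library-size scaling, which moved the median of all genes by -0.20 with HS and 0.24 with AS, put 21% of the HS calls on the higher side against 45.3%, and size factors by the RLE method 57.5%.

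The granule fraction carried the induced mRNAs as well. With THAP, Gadd45g rose 21.6-fold in granules (log2 4.43 ± 0.60, SE, n = 3; edgeR adjusted p = 0.000194), and Nr4a1 and Egr2 rose 10.7-fold and 10.9-fold. Gstm1 fell 5.37-fold, Ccnf 5.10-fold and Acsf2, an acyl-CoA synthetase gene, 4.38-fold. With HS, Atf3 rose 25.4-fold and Hspa1a 20.9-fold (4.38 ± 0.42, n = 2; edgeR adjusted p = 3.45e-05). Ndc80, a kinetochore gene, Npm1, the nucleolar nucleophosmin gene, and Dars, a transfer RNA synthetase gene, fell 3.66-fold, 3.48-fold and 3.47-fold. With AS, Atf3, Egr1 and Hspa1a rose 8.63-fold, 7.58-fold and 6.70-fold. Clec2d, a lectin gene, Rps27l, a ribosomal protein paralog, and Atp5e, a subunit gene of ATP synthase, fell 13.7-fold, 9.12-fold and 8.95-fold. Over the alternatives and left-out libraries or replicates, their log2 changes ranged over -4.68 to -3.25, -4.10 to -1.53 and -3.95 to -1.37.

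By list, THAP raised 14 of 29 unfolded protein response genes (16 adjusted over the list alone, or adjusted p = 0.163 with an estimated correlation) and 15 of 23 immediate early genes in granules (18 alone, or adjusted p = 0.0796 with an estimated correlation). THAP lowered 16 of 28 cell-cycle genes (20 alone, or adjusted p = 0.163 with an estimated correlation), 32 of 74 oxidative phosphorylation genes (56 alone, or adjusted p = 0.347 with an estimated correlation) and 8 of 26 heat-shock genes (10 alone, or adjusted p = 0.163 with an estimated correlation). AS lowered 81 of 81 ribosomal protein mRNAs, 72 of 74 oxidative phosphorylation mRNAs, 67 of 69 histone mRNAs and 16 of 28 cell-cycle mRNAs in granules (81, 72, 67 and 16 adjusted over the list alone), each with adjusted p = 0.182 with an estimated correlation. HS lowered 5 of 20 translation factor and related mRNAs (11 alone, or adjusted p = 0.366 with an estimated correlation). The granule counts were 2416 genes with THAP (1054 up, 1362 down; 4802 with the replicate block), 365 with HS (198 up, 167 down) and 4895 with AS (1714 up, 3181 down) by edgeR's quasi-likelihood test.

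Single granule libraries moved those counts. Without DMSO 1 or THAP 1 the THAP count was 1346 or 1447. Without H2O 1, H2O 2, HS 1 or HS 2 the HS count was 591, 1136, 35 or 71. Without H2O 1 or AS 1 the AS count was 2181 or 2603. The spread of the compared groups alone gave 1020 calls with THAP, 0 with HS (551 at an unadjusted p under 0.05; 1034 by DESeq2 on all libraries) and 1660 with AS. Without the replicate 2 granule libraries of H2O, HS and AS, the HS count was 9. Scaling by library size alone raised the median of all genes by 0.23, 0.32 and 0.44 (log2). The share of higher calls went from 43.6% to 69.9% with THAP, from 54.2% to 96.8% with HS and from 35% to 61.1% with AS.

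Redistribution was the question of the series. THAP shifted Spred1, an inhibitor of Ras signalling (NM_033524, 2, 117121374 to 117182279, mm10), towards granules. It stood at 38.7 CPM ± 3.96 in cytoplasm and 34.7 ± 5.99 in granules with DMSO, and at 18.7 ± 8.44 and 105 ± 19.6 with THAP (SD, n = 3). Its ratio changed by 2.64 ± 0.49 (log2, SE; edgeR adjusted p = 0.0180). Tmem170b (7.40-fold), Plcxd2 (6.62-fold), the ubiquitin protease gene Usp31 (6.04-fold) and Rc3h2 (6.02-fold), an RNA-binding ubiquitin ligase of the Roquin family, had shifts of similar size. Among 40 proto-oncogenes, Met (2.16 ± 0.48), Crk, an adaptor (1.64 ± 0.39), Mdm2, the ubiquitin ligase of p53 (1.36 ± 0.30), and Crkl (1.30 ± 0.31) rose in the ratio. Of the list, 4 rose and 6 adjusted over the list alone (camera adjusted p = 0.000462, or adjusted p = 0.176 with an estimated correlation). Edem1, which directs misfolded glycoproteins to degradation, rose 2.98-fold. Ahnak had a ratio change of 2.55 ± 0.64 and missed the threshold (edgeR adjusted p = 0.0506; 0.00543 with the replicate block).

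Other genes fell in the ratio with THAP. Hspa8, the constitutive HSP70 (9, 40800984 to 40810087), stood at 2090 CPM ± 123 in cytoplasm and 2480 ± 118 in granules with DMSO, and at 1990 ± 149 and 917 ± 107 with THAP. The ratio fell 2.57-fold (-1.36 ± 0.26; edgeR adjusted p = 0.0204). The cochaperone gene Fkbp4 (-1.61 ± 0.35), the ubiquitin gene Ubb (-1.45 ± 0.34) and Hsp90ab1 (-1.31 ± 0.32) fell too. The heat-shock list had 4 of 26 genes lower over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000335, or adjusted p = 0.176 with an estimated correlation). The glycolytic enzyme gene Eno1 (-1.63 ± 0.40), the kinase gene Cdk1 (-1.12 ± 0.28), the replication clamp gene Pcna (-0.98 ± 0.24), the intermediate filament gene Vim (-1.21 ± 0.30) and Uqcrc2, a subunit of respiratory complex III (-1.37 ± 0.31), fell as well. Of the list, 3 of 74 oxidative phosphorylation genes fell over all genes and 3 adjusted over the list alone (camera adjusted p = 1.76e-10, or adjusted p = 0.457 with an estimated correlation). Ribosomal protein mRNAs had 0 of 81 calls by edgeR, 0 adjusted over the list alone, and a median of -0.19 that turned to 0.03 with library-size scaling (camera adjusted p = 0.0355, or 0.068 with the replicate block, or adjusted p = 0.845 with an estimated correlation).

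The ratio changed in 271 genes with THAP, 196 up and 75 down (edgeR's quasi-likelihood test), and in 1857 with the replicate block (1124 up, 733 down). Without DMSO cytoplasm 1 or 2 the count was 35 or 3, without DMSO granule 1 or 2 it was 12 or 169. Without THAP cytoplasm 2 or 3 it was 19 or 53, and without THAP granule 1 or 3 it was 3 or 86. None of the 26 genes followed up kept its call without each of the 12 libraries in the model without the block. With the block on all libraries, 26 kept it. With replicates 1 and 2 alone in the blocked model the count was 8, DESeq2 called 1154 and the spread of these groups alone gave 601. Library-size scaling raised the median ratio change of all genes by 0.19 and the share of higher calls from 72.3% to 89.0%, and size factors by the RLE method lowered that share to 62.3%.

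With HS, Rhou, a small GTPase gene (8, 123653929 to 123663884, mm10), moved from 100 CPM ± 17.2 in cytoplasm and 50.9 ± 9.09 in granules with H2O to 39.9 ± 6.23 and 157 ± 13.7 (SD, n = 2). Its ratio changed by 2.95 ± 0.36 (log2, SE; edgeR adjusted p = 0.00151). The transcription factor gene Pou6f1 (9.42-fold), the polarity gene Pard6b (8.09-fold) and the zinc finger gene Atmin (7.57-fold) rose by as much. Of 40 proto-oncogenes, 6 rose and 6 adjusted over the list alone, among them Ski (2.49 ± 0.37), the kinase gene Abl1 (1.70 ± 0.37), the survival gene Mcl1 (1.66 ± 0.38) and Mdm2 (1.56 ± 0.38; camera adjusted p = 2.68e-05, or adjusted p = 0.103 with an estimated correlation). Npm1 fell 7.05-fold in the ratio (-2.82 ± 0.60) and Eif3e, a translation initiation factor subunit, 5.39-fold. Vim fell 4.44-fold (-2.15 ± 0.37; edgeR adjusted p = 0.00430), from 1500 CPM ± 46.0 and 1690 ± 230 with H2O to 2370 ± 646 and 603 ± 36.3 in cytoplasm and granules. Of 20 translation factor and related mRNAs, 9 fell and 12 adjusted over the list alone (camera adjusted p = 2.11e-09, or adjusted p = 0.267 with an estimated correlation). Hspa8 (-1.75 ± 0.32), Ubb (-1.76 ± 0.42) and Hsp90ab1 (-1.69 ± 0.39) fell among 26 heat-shock genes, 5 adjusted over the list alone (camera adjusted p = 0.00948, or adjusted p = 0.493 with an estimated correlation). The endoplasmic reticulum chaperone genes Hspa5 (-1.71 ± 0.46), Hsp90b1 (-1.77 ± 0.50) and Calr (-1.51 ± 0.37) fell. Rpl5, Rpl4 and Rpl7 fell 3.00-fold, 3.02-fold and 2.71-fold. Of 81 ribosomal protein mRNAs, 3 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 3.47e-11, or adjusted p = 0.493 with an estimated correlation).

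The ratio changed in 721 genes with HS, 484 up and 237 down (edgeR's quasi-likelihood test). The count was 200 and 185 without H2O cytoplasm 1 or 2, 1638 without H2O granule 2, 109 without HS cytoplasm 2, and 218 and 377 without HS granule 1 or 2. Pou6f1, Pard6b, Rhou, Atmin, Ski and Vim, 6 of 35 genes followed up, kept their calls without each of the 8 libraries. Without the replicate 2 granule libraries of H2O, HS and AS the count was 267, the spread of these groups alone gave 0 (2305 at an unadjusted p under 0.05), and DESeq2 called 1410. Library-size scaling raised the median ratio change of all genes by 0.54, gave 1527 calls and put 96.7% of them on the higher side against 67.1%. The calls of Hspa8, Vim, Npm1, Eif3e, Rpl5 and Rpl4 held under it and those of Hspa5, Hsp90b1, Calr, Hsp90ab1, Ubb and Rpl7 did not.

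With AS, more genes fell than rose in the ratio. The AS cytoplasm libraries themselves stood apart. Malat1 was at 1930 and 1190 CPM there, against 305 and 438 in H2O cytoplasm and at most 523 in the other cytoplasm libraries. The 11 nuclear noncoding RNAs summed to 3700 and 2550 CPM there, against 1270 and 1610 in H2O cytoplasm. How far this moved the ratios between the AS fractions was not tested. Npm1 fell 8.63-fold (log2 -3.11 ± 0.60, SE, n = 2; edgeR adjusted p = 0.0123), the nucleolin gene Ncl 10.5-fold, Dars 10.8-fold, Eif3e 6.98-fold and Vim 5.12-fold. Hspa8 fell 4.31-fold (-2.11 ± 0.32; edgeR adjusted p = 0.00660), from 2080 CPM ± 137 and 2440 ± 453 with H2O to 1920 ± 473 and 523 ± 134 in cytoplasm and granules. Ubb, Hsp90ab1 and Fkbp4 fell 4.39-fold, 3.80-fold and 3.68-fold. Of 26 heat-shock genes, 7 fell and 8 adjusted over the list alone (camera adjusted p = 2.36e-05, or adjusted p = 0.164 with an estimated correlation). Of 20 translation factor and related mRNAs, 11 fell and 18 adjusted over the list alone (camera adjusted p = 1.26e-11, or adjusted p = 0.164 with an estimated correlation). Uqcrc2 (-2.26 ± 0.38), Ndufv1, of respiratory complex I (-2.06 ± 0.43), and Atp5b (-1.88 ± 0.38) were among 12 of 74 oxidative phosphorylation mRNAs that fell (65 adjusted over the list alone; camera adjusted p = 1.22e-17, or adjusted p = 0.447 with an estimated correlation). Rpl5 and Rpl4 were among 6 of 81 ribosomal protein mRNAs (61 alone, or adjusted p = 0.53 with an estimated correlation). Of 28 cell-cycle genes 4 fell, Pcna (-1.78 ± 0.30), Tyms, Bub1 and Mcm7 (7 alone, or adjusted p = 0.364 with an estimated correlation). Of 21 oxidative stress genes 3 fell, the thioredoxin gene Txn1 (-1.85 ± 0.40), the peroxiredoxin gene Prdx1 and the cystine transporter gene Slc7a11 (6 alone; camera adjusted p = 0.0233, or adjusted p = 0.558 with an estimated correlation). The ratio rose for Neurl1a, a ubiquitin ligase gene (6.38-fold), Pou6f1 (5.24-fold), Atxn1l, a paralog of ataxin 1 (5.23-fold), and Atmin (5.20-fold). Of 40 proto-oncogenes 2 rose, Ski (3.37-fold) and Abl1 (3.01-fold; 2 alone; camera adjusted p = 0.0233, or adjusted p = 0.364 with an estimated correlation).

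In total 706 genes changed in the ratio with AS, 210 up and 496 down (edgeR's quasi-likelihood test). Without H2O cytoplasm 1 or 2 the count was 51 or 1, without H2O granule 2 it was 1881, without AS cytoplasm 2 it was 58, and without AS granule 1 or 2 it was 6 or 255. None of the 39 genes followed up kept its call without each of the 8 libraries. Without the replicate 2 granule libraries of H2O, HS and AS it was 1544, the spread of these groups alone gave 0 (2580 at an unadjusted p under 0.05), and DESeq2 called 1598. Library-size scaling raised the median ratio change of all genes by 0.19 and put 54.6% of the calls on the higher side against 29.7%. The calls of Hspa8, Npm1, Eif3e, Vim, Ncl and Uqcrc2 held under it.

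The redistribution profiles of the stresses were compared across 15616 genes, which are not independent replicates. HS and AS, which share the H2O libraries, had 166 genes higher in both and 189 lower in both, where independent lists would share 6.51 and 7.53, and 0 genes called in opposite directions. Their fold changes correlated at r = 0.615 (Spearman rho = 0.678). Unchanged groups simulated against the same controls gave r = 0.533 on average over 100 simulations, and the covariance was 1.01 against 0.784 simulated, a difference of 0.228. With 2 control libraries per fraction the controls could not be split, so part of the overlap may come from them. THAP and HS, which share no library, had 96 genes higher in both (6.07 for independent lists), 51 lower in both (1.14) and 0 opposite, with r = 0.356 and rho = 0.473. Edem1, Mdm2, Hspa8, Hsp90ab1, Ubb and Vim were among the genes called with both. The correlation was 0.588 in replicate 1 and 0.168 in replicate 2, and 0.108 without replicate 1. THAP and AS had 44 higher in both (2.64), 61 lower in both (2.38) and 1 opposite, with r = 0.187 and rho = 0.333. That correlation was 0.399 in replicate 1 and 0.184 in replicate 2, and 0.053 without replicate 1.

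Differences between stresses were tested directly. THAP against HS and THAP against AS gave 0 genes each by edgeR (698 and 1325 at an unadjusted p under 0.05; 6 and 0 by DESeq2; 0 and 0 with the replicate block), and THAP against AS gave 2 without H2O granule 1. HS against AS gave 1 gene by edgeR (1019 at an unadjusted p under 0.05), and 0 when any 1 of the 8 HS and AS libraries was left out. DESeq2 called 51 genes, the spread of the compared groups alone gave 113, and the replicate block gave 220. Library-size scaling shifted the median difference of all genes by 0.34 and gave 0.

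Longer mRNAs had the larger rises in the ratio. Across 14312 protein-coding genes with a known length, Spearman's rho between mRNA length and redistribution was 0.363 with THAP (0.339 ± 0.05 over replicates, SD, n = 3), 0.216 with HS (0.359 and 0.036 in replicates 1 and 2) and 0.201 with AS (0.322 and 0.059). From the shortest to the longest quintile, the median redistribution went from -0.31 to 0.57 with THAP, from -0.63 to 0.09 with HS and from -0.68 to 0.04 with AS. Of 2863 genes in the longest quintile, 87 rose and 1 fell with THAP (229 and 11 adjusted over the list alone, camera adjusted p = 1.6e-11, or adjusted p = 0.176 with an estimated correlation), 128 and 16 with HS (adjusted p = 0.523 with an estimated correlation) and 75 and 33 with AS (adjusted p = 0.53 with an estimated correlation). Of 2863 in the shortest quintile, 5 rose and 20 fell with THAP (0 and 3 adjusted over the list alone), 19 and 62 with HS and 6 and 159 with AS (camera adjusted p = 5.14e-07, 2.62e-05 and 5.28e-05; adjusted p = 0.364, 0.493 and 0.53 with an estimated correlation). The granule-to-cytoplasm ratio itself rose with length in each group, with rho from 0.335 with DMSO to 0.480 with THAP. The list of 40 giant-protein mRNAs had a median redistribution of 1.12 with THAP, -0.03 with HS and -0.27 with AS. The median of all genes was 0.04, -0.17 and -0.19. With library-size scaling the HS median of the list turned to 0.51.

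Motifs in the 3' untranslated region showed the same order within quintiles of its length. Genes with an AU-rich nonamer (1111) lay above those without by 0.186 with THAP (replicates 0.192 ± 0.022, SD, n = 3), 0.205 with HS (0.169 ± 0.126, n = 2) and 0.192 with AS (0.175 ± 0.093, n = 2). Genes with a Pumilio binding motif (3607) lay above by 0.293 (0.290 ± 0.026), 0.226 (0.238 ± 0.324) and 0.112 (0.112 ± 0.219), so that with HS and AS the Pumilio difference did not exceed the spread between replicates. Among the 3607, 106 rose and 8 fell with THAP (262 and 28 adjusted over the list alone, camera adjusted p = 2.36e-08, or adjusted p = 0.176 with an estimated correlation), and among the 1111, 41 rose and 2 fell (98 and 11 adjusted over the list alone, camera adjusted p = 4.47e-05, or adjusted p = 0.176 with an estimated correlation).

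**Figure D3:**
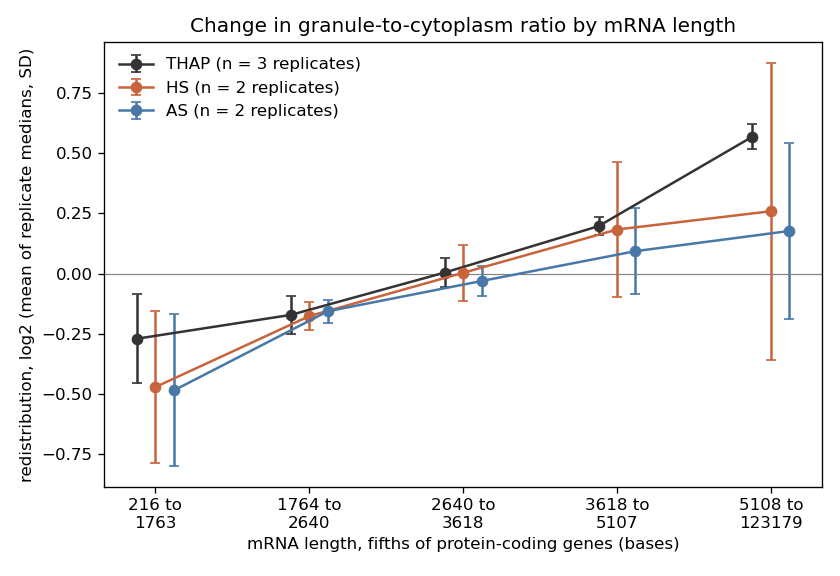
Redistribution (log2, vertical axis) in quintiles of mRNA length (horizontal axis, bases); points are means over replicates of the median per quintile and bars their SD, with n = 3 for THAP and n = 2 for HS and AS. The THAP medians climb from quintile to quintile, and the bars of HS and AS in the longest quintile are wider than the distance of their points from 0.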

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

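The test of mRNA length against gene span and against GC content was planned, and no test in this part was chosen only after its result was seen. Redistribution differed between stress and control in 271 genes with THAP, 721 with HS and 706 with AS (edgeR's quasi-likelihood test). Between HS and AS, 1 gene differed in it (edgeR's test of the difference), and 0 when any 1 of the 8 HS and AS libraries was left out. These counts moved with single libraries, as given beside each result.

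Of the 10 splits of the libraries of each DMSO and THAP comparison (6 libraries, or for redistribution 12, split with both fractions of a number kept together), 1 called as many genes, the real one. The real counts were 202 and 4800 between fractions with DMSO and THAP, 444 in cytoplasm, 2416 in granules and 271 for redistribution. The highest other split called 0 genes in each, also among the splits that part all 3 pairs. Each other split mixed libraries of the real groups in the model without the block, so real differences added to its spread. Low counts there could follow from this alone and do not support the real count. With 10 splits a share under 0.05 cannot be reached.

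Over all protein-coding genes, longer mRNAs had larger rises in the granule-to-cytoplasm ratio with each stress. The list of 40 giant-protein mRNAs had a median redistribution of 1.12 with THAP, but of -0.03 with HS and -0.27 with AS. Reads from introns of unspliced RNA would tie the ratio to gene span, and the highest partial rho of span given mRNA length was -0.010 over the 3 stresses. Given GC content and mean level, 93%, 121% and 176% of the length correlation was kept with THAP, HS and AS. The correlation of GC content itself with redistribution was unsteady with HS, at -0.246 and 0.442 in replicates 1 and 2. The tests went against intron reads and against GC content or level as the source of the length correlation. Other technical explanations were not tested. A length-dependent move of mRNA into granules may remain as a hypothesis, found and tested on the same data, and replicate 2 alone gave rho of 0.036 with HS and 0.059 with AS.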

How the results depend on the processing

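Counts of called genes moved by more than 1.5 times under several alternatives, which are listed by setting. The cause was not tested unless named. No named gene reversed its direction. Lists were tested again only with the replicate block and with an estimated correlation, for which the direction was not read anew. With the block no list reversed past the threshold. Under library-size scaling some list medians changed sign, such as ribosomal proteins for redistribution with THAP (-0.19 to 0.03) and giant proteins with HS (-0.03 to 0.51). RLE factors and leaving out structural RNA moved no count by more than 1.5 times.

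Scaling by library size alone gave 317 genes between the DMSO fractions, 567 in cytoplasm with HS and 24 with AS, 725 in granules with HS, 471 and 1527 for redistribution with THAP and HS, and 0 for HS against AS. DESeq2 gave 835 and 2920 between the DMSO and H2O fractions. In cytoplasm it gave 912, 381 and 840 (THAP, HS, AS), in granules 1034 with HS, and for redistribution 1154, 1410 and 1598. It gave 6 for THAP against HS and 51 for HS against AS.

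Without a filter the counts were 109 between the DMSO fractions, 289 and 157 in cytoplasm with THAP and HS, 118 in granules with HS, 145, 455 and 400 for redistribution and 0 for HS against AS. With at least 1 CPM in each group mean they were 337 between the DMSO fractions, 84 in cytoplasm with HS, 493 for redistribution with THAP and 2 for HS against AS.

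With the replicate block the fractions differed in 1651, 7665, 4407, 8069 and 7657 genes (DMSO, THAP, H2O, HS, AS). The counts were 1917, 1116 and 1765 in cytoplasm, 4802, 2023 and 7683 in granules, 1857, 2528 and 2849 for redistribution and 220 for HS against AS. In the groups of 2, deviations of same-numbered libraries correlated at 0.12 to 0.55 between the fractions of a treatment and between a stress and H2O in a fraction. Over all pairs of these groups they ranged from -0.459 (H2O granule and AS cytoplasm) to 0.554, with -0.0887 between HS and AS cytoplasm and -0.0654 between HS granule and AS cytoplasm. The labels do not tie the numbers together, and the values do not show that they pair the libraries. Of 176 list results, the block weakened 4 and strengthened 7. Of the same 176, an estimated correlation weakened 94. Of the named genes called, the block kept each call, and it strengthened 10 named results that had missed the threshold.

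With the spread of the compared libraries alone, edgeR called 0 between the DMSO and H2O fractions (2201 and 1699 at an unadjusted p under 0.05) and 6912 after AS. In cytoplasm it called 190, 916 and 2492, in granules 1020, 0 and 1660, for redistribution 601, 0 and 0, and 113 for HS against AS.

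The alternatives of this paragraph were added after the data had been seen. The block without the 39 ribosomal RNA-like genes gave 1649, 7670, 4414, 8066 and 7656 between fractions, 1912, 1113 and 1790 in cytoplasm, 4810, 2024 and 7675 in granules, 1864, 2532 and 2854 for redistribution and 217 for HS against AS. Without the block, leaving these genes out moved no count by more than 1.5 times, nor did the transcript with the lowest count per symbol. The block with replicates 1 and 2 alone gave 3432 and 6982 between the H2O and AS fractions, 824 and 273 in cytoplasm with HS and AS, 1416 in granules with HS, 8, 1951 and 2267 for redistribution and 110 for HS against AS. Without the replicate 2 granule libraries of H2O, HS and AS, the counts were 2 and 3340 between the H2O and HS fractions, 9 in granules with HS, 267 and 1544 for redistribution with HS and AS and 0 for HS against AS.

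Where a library was left out of a group of 2, the lone library was assumed to vary like the other groups. Over left-out libraries and replicates, the counts between fractions ranged over 0 to 164 (DMSO), 662 to 4099 (THAP), 0 to 5306 (H2O), 0 to 6617 (HS) and 0 to 5894 (AS). In cytoplasm they ranged over 0 to 367, 0 to 484 and 0 to 35, in granules over 0 to 2153, 0 to 1136 and 0 to 6507, and for redistribution over 0 to 225, 0 to 1638 and 0 to 1881. Those between stresses ranged over 0 to 0, 0 to 2 and 0 to 30. The low ends of these ranges were reached without replicate 1. The H2O, HS and AS groups then held a lone library each, and the spread came from replicates 2 and 3 of DMSO and THAP. As replicate 3 stood apart from replicate 2, low counts in that fit do not show what replicate 1 contributed. Between the THAP fractions 662 genes were called in it. Without replicate 3, redistribution with THAP was called for 1 gene.

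Among genes at a mean log2 CPM of at least 3, redistribution correlated at 0.503 between THAP and AS and 0.872 between HS and AS, and with length at 0.498 with THAP. With coding length the THAP rho was 0.176. Over left-out replicates, the correlations ranged over 0.108 to 0.395 (THAP and HS), 0.053 to 0.234 (THAP and AS) and 0.570 to 0.660 (HS and AS). The length rho ranged over 0.340 to 0.371, 0.024 to 0.330 and 0.055 to 0.305 (THAP, HS, AS).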

Other observations

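The tests on genes lower in replicate 3, on chromosome spans after thinning and on the correlation with Rn45s were chosen only after the result was seen. The replicate 3 libraries of DMSO and THAP expressed a different set of genes from replicates 1 and 2. Pappa2, a protease of growth factor binding proteins, averaged 166 CPM in replicates 1 and 2 and 0.237 in replicate 3, a log2 difference of -8.65 ± 0.65 (SD, n = 4 groups). Fat4, a large cadherin, averaged 212 and 0.432. Itgb7, an integrin, averaged 3.57 and 349 (6.57 ± 0.32), Grk5, a receptor kinase, 9.01 and 338, and Kcnn4, a potassium channel, 8.96 and 329.

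Of 79 small structural RNA genes, 27 fell in granules with AS (31 adjusted over the list alone, camera adjusted p = 4.34e-09, or adjusted p = 0.282 with an estimated correlation). Of 20 cholesterol synthesis genes, 1 rose in cytoplasm with THAP (4 alone, camera adjusted p = 0.00361, or adjusted p = 0.61 with an estimated correlation), and 2 rose and 8 fell in granules with AS. Of 8 immune markers 2, of 6 epithelial markers 2 and of 8 endothelial markers 1 were lower in granules than in cytoplasm after HS (camera adjusted p = 0.189, 0.189 and 0.457). The median of the endothelial list there turned from -0.39 to 0.10 with library-size scaling. In the differences between stresses no list had a called member (0 by edgeR).

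RNA of another cell type mixed into replicate 3 would add transcripts without removing others, and 73 genes at a mean log2 CPM of at least 3 were lower by at least 5 (log2). Markers of other cell types were higher in replicate 3. Endothelial markers summed to 123 to 230 CPM there, against 23.1 to 44.9 in DMSO and THAP replicates 1 and 2. Immune markers summed to 42.5 to 88.2 against 13.5 to 28.5. The 73 genes therefore argue against mixing as the whole source, not as a part of it. Chromosome medians of replicate 3 minus replicates 1 and 2 spanned 0.76, against 0.16 between replicates 2 and 1 and at most 0.21 in 1000 shuffles. After thinning to 1 total, 83.3% of 144 genes still differed, below the 90% set beforehand, and the span was 0.739. Another clone, line or drifted culture may therefore be the source, which these libraries cannot name. The DMSO and THAP comparisons hold replicate 3 in both groups.

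A set of 39 genes was high in the replicate 2 granule libraries of H2O, HS and AS, with 12.5%, 6.13% and 4.81% of their counts. Ribosomal RNA reads counted over these genes may explain it. Over 18 other libraries the median correlation of the set with Rn45s was 0.65, under the 0.7 that would have favoured this source and above that of 100 random lists (-0.10 to 0.19). Centred on group means it was 0.76 (random lists -0.14 to 0.06), so the values fall on both sides of that mark and this stays open. Depth did not account for it, as 100% of the set passed its rule after thinning.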
